A study of Homo sapiens with 6 samples.

How the data were processed

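The series holds 6 RNA-seq libraries of T24 cells, 3 labelled control and 3 labelled TGF-β treated (written TGF-b1 here), all at day 2. The labels give a growth medium with 10% serum, a treatment at 10 ng/ml for 48 h, total RNA, and 150 bp paired-end sequencing on an Illumina NovaSeq. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used with build hg38. The strand setting, the kit, the annotation release and any trimming are not given in the sources used here.

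Per the file headers and labels, the deposited values are FPKM, fragments scaled to gene length and to the library's total, in 1 table of 6 columns and in 6 files of 1 column that hold the same values. The first 11 rows of each column are mapping totals and were kept out of every fit. The remaining 58735 rows are genes by symbol, with 57167 distinct names. In 27 of them a spreadsheet had turned the symbol into a calendar date; 16 of these were tested, and none is named.

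The exon lengths of GENCODE release 29 on GRCh38 were matched to the rows by symbol, and 58708 rows had a name in that annotation. Multiplying each FPKM by its length and by 1 value per library gave whole numbers of fragments for 99.999% of 126561 values above 0, to within 0.05 of a whole number. These fragments give the depths, 20789414 to 23774598 per library, and the coordinates printed are from this annotation. The FPKM denominators were 0.960 to 1.03 times the total assigned fragments. They equal a median-of-ratios scaling factor times the geometric mean total to within 0.0138%, so the deposited FPKM already carry a scaling between libraries that the labels do not mention. A gene with 0 fragments can hold up to 3 at the 95% level, which covers counting error only.

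No pair of libraries was a duplicate: chi-square per degree of freedom on the recovered fragments was 6.06 to 26.2 within groups, where 1 is sampling noise.

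The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend and robust estimation, over the 11363 genes with at least 1 FPKM in at least 3 libraries. Treatment was the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All adjusted p-values printed for genes come from this test unless another setting is named. The group totals, the test, 41 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The design allowed for either counts or FPKM, and FPKM decided the test.

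Of the 41 lists, 37 had at least 3 measured members and were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, adjusted by Benjamini-Hochberg over the lists. By camera 10 lists passed, 6 higher and 4 lower, 0 passed with an estimated correlation (smallest adjusted p 0.32), and 18 passed by fry, which asks only whether the members move on balance in 1 direction. Of the lists past camera, all but antigen presentation and the ribosomal proteins passed by fry. Past fry but not camera were the mesenchymal markers, EMT transcription factors, integrins, matrix glycoproteins and matrix proteases. So were the basal, luminal, interferon, early-response and hypoxia lists. Symbols that name more than 1 gene were left out of the lists. Some genes sit in more than 1 list, such as COL1A1 and FN1. List means per library were compared by an exact two-sided permutation test, which for 3 against 3 cannot go below 0.1.

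Genes were named by a rule, and the values of a few genes that meet it are left out. The rule takes the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with non-overlapping groups and a mean of at least 5 FPKM in the higher group. It also takes up to 4 members of each list described, those past the threshold first and then by size of change. CDH1, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, TWIST1, CD44, SOX2, KLF4, MYC, POU5F1, NANOG, ALDH1A1, PROM1, SMAD7, TGFB1, CD274 and ID1 are given whatever their values, and ACTB and GAPDH as reference genes.

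Simulated data with known fold changes were drawn from these libraries' means and the median spread of genes of similar abundance. Genes varied independently there, so recovery in the real libraries can be lower. The test was run on these simulated data. Without a GC trend it recovered 64.2% of 53 genes changed 1.5-fold, 95.8% of 71 changed 2-fold and 95.7% of 70 changed 4-fold, with 12 false calls among 11285 genes. With a GC trend left in, it recovered 40.3% of 72 genes changed 1.5-fold with 17 false calls among 11288 genes, and with the trend removed 65.3% with 25.

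The alternatives tried were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, other scalings, limma without trend or robust estimation, the replicate number as a block, leaving out each library, and protein-coding genes only. Added after the data were seen were limma's voom on the recovered fragments, scaling to total fragments, removal of a loess trend (span 0.3) with GC content and exon length from each library, and that removal combined with the block or without control 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.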

Results

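RNA from T24 cells, an established human line from a bladder urothelial carcinoma, was sequenced as 6 libraries of 150 bp read pairs. In 3 libraries the cells had received TGF-β1 at 10 ng/ml for 48 h, and 3 libraries came from cells kept without it. TGF-β1 is a secreted cytokine that acts through receptor kinases and SMAD transcription factors and is widely used to induce epithelial-to-mesenchymal transition (EMT) in cultured carcinoma cells. The mapping totals deposited with the values give 53591796 to 60200816 reads per library, of which 93.5 to 95.5% mapped. Each library held 20789414 to 23774598 fragments assigned to genes, and 11229 to 11405 genes reached 1 FPKM. At this depth 3 fragments on a gene of 2000 bp correspond to 0.0625 to 0.0701 FPKM. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

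The comparison asks which transcripts differ between T24 cells with and without TGF-β1, in a series whose title concerns tumour stemness, EMT and response to immunotherapy. The largest rises included genes of TGF-β feedback and of the matrix. PMEPA1, a membrane protein that restrains TGF-β signalling, rose from 14.1 ± 1.51 to 68.4 ± 6.12 FPKM (SD, n = 3), a ratio of 4.85. FN1, which encodes fibronectin, rose from 54.5 ± 4.98 to 159 ± 7.34 FPKM, a ratio of 2.91. The largest falls included GAL3ST1, a sulfotransferase of glycolipids, from 19.7 ± 3.15 to 4.52 ± 1.07 FPKM, and CSF3, the granulocyte colony-stimulating factor, from 120 ± 13.7 to 48.2 ± 6.72 FPKM. On the log2(FPKM + 1) scale, which understates the change of low genes, these were changes of 2.20 for PMEPA1 (SE 0.11, adjusted p = 7.1e-06), 1.53 for FN1 (SE 0.10, adjusted p = 3.6e-05), -1.91 for GAL3ST1 (SE 0.15, adjusted p = 0.00031) and -1.30 for CSF3 (SE 0.12, adjusted p = 0.00038).

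Among 11363 genes tested, 277 passed an adjusted p of 0.05, 130 higher and 147 lower with TGF-β1. Of them 32 changed at least 2-fold on the log2(FPKM + 1) scale, 19 higher and 13 lower. Here and below, 2-fold counts are on the scale fitted. It leaves out low genes with larger FPKM ratios, such as COL1A1 at 3.38, and a pseudocount of 0.1 gave 71. By annotated type, 120 of the 130 higher and 132 of the 147 lower genes were protein-coding, and 6 higher and 7 lower were long non-coding. The count depended on single libraries. Without control 3 it was 3280 (1408 higher, 1872 lower, 64 at least 2-fold), without control 1 it was 124 (80 higher, 44 lower), and without control 2 it was 176 (100 higher, 76 lower). Without TGF-b1 2 or TGF-b1 3 it was 152 each (82 higher and 70 lower, 86 higher and 66 lower). Of 554 distinct genes measured in the lists described here, 59 passed, against 237 without control 3 and 36 without control 1. It was 502, with 289 higher and 213 lower, after a trend with GC content and gene length was removed from each library, and 235 genes were in both sets. It was 15 with no filter on low genes, 500 at a minimum of 5 FPKM, 846 over protein-coding genes alone, 767 with the replicate number as a block and 1063 by voom.

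Other large rises were in TUBA4A, an alpha-tubulin, from 2.74 ± 0.651 to 16.2 ± 1.52 FPKM, in FSTL3, a secreted binder of activin, from 3.76 ± 1.34 to 16.1 ± 0.916 FPKM, and in ADAM19, a membrane metalloprotease, from 1.81 ± 0.0813 to 6.96 ± 0.315 FPKM. They continued with ANGPTL4, a secreted inhibitor of lipoprotein lipase, from 52.8 ± 8.70 to 140 ± 11.2 FPKM, and EPHB2, an ephrin receptor, from 9.97 ± 0.884 to 27.4 ± 2.04 FPKM. SMAD7, the inhibitory SMAD, rose from 2.35 ± 0.30 to 6.39 ± 0.932 FPKM and SKIL, a SMAD co-repressor, from 3.48 ± 0.682 to 8.58 ± 0.0204 FPKM. The remaining large falls were in G0S2, an inhibitor of triglyceride lipase, at 0.373 of the control mean, in the transcription factor CEBPD at 0.418, in the calcium sensor HPCAL1 at 0.422, and in the membrane protein TMEM158 at 0.378. LCN2, a siderophore-binding lipocalin, fell to 0.365 of the control mean, the pentraxin PTX3 to 0.458, the ERK phosphatase DUSP5 to 0.455 and the plakin PPL to 0.460. The CEBPD call was lost without control 1, control 2 or TGF-b1 2 (adjusted p 0.063 to 0.093), and those of the other genes of this paragraph, of PMEPA1, FN1, GAL3ST1 and of CSF3 held whichever library was left out.

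**Figure D1:**
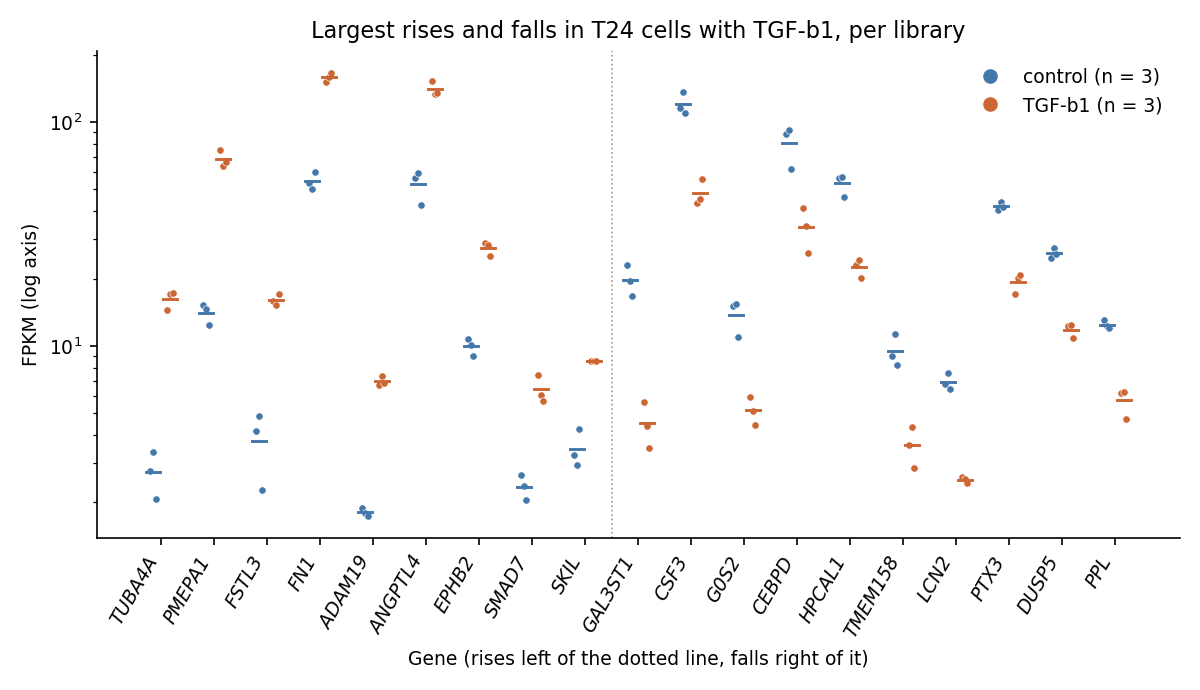
Each point is the FPKM of 1 library on a log axis, for control (n = 3) and TGF-b1 (n = 3) libraries, and horizontal bars are group means. The genes left of the dotted line rose and those right of it fell, with no overlap of the groups because the rule that chose them asks for it, for example PMEPA1 from a mean of 14.1 to 68.4 FPKM and GAL3ST1 from 19.7 to 4.52 FPKM.

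In the GRCh38 annotation, PMEPA1 lies on chromosome 20 at 57648392 to 57711536, FN1 on chromosome 2 at 215360440 to 215436172, GAL3ST1 on chromosome 22 at 30554635 to 30574587 and CSF3 on chromosome 17 at 40015361 to 40017813. Whether the counting used strand is not given in the sources used here, so fragments of genes that overlap on opposite strands cannot be told apart. PMEPA1 overlaps the antisense RNA NKILA, named after its value was seen, which itself rose from 1.46 ± 0.128 to 4.29 ± 0.615 FPKM (log2 change 1.10, adjusted p = 0.00051). TUBA4A, on chromosome 2 at 219249711 to 219278170, overlaps STK16 and TUBA4B on the opposite strand and belongs to a family of closely related tubulin genes. STK16 stood at 7.96 ± 1.28 and 7.74 ± 0.465 FPKM (adjusted p = 0.89). ADAM19 overlaps CYFIP2, which stood at 8.77 ± 0.413 and 8.67 ± 0.811 FPKM (adjusted p = 0.92), ANGPTL4 overlaps RAB11B-AS1 and PTX3 overlaps VEPH1 in the same way. STK16 and CYFIP2 were looked up after the results were seen.

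Genes known to respond to TGF-β rose as a group. Of 20 measured members of the list, 10 rose and 0 fell, against 14 and 1 when adjusted over the list alone, and the median log2 change was 0.51. The members that rose included PMEPA1, FSTL3, SMAD7, SKIL, COL1A1 and, named after their values were seen, TGFBI, LTBP2, BMF and KLF10. LTBP2, a matrix protein of microfibrils, rose from 11.1 to 23.4 FPKM. BMF, a pro-apoptotic BH3-only protein, rose from 1.52 to 3.73 FPKM and TGFBI, a secreted matrix protein, from 0.800 to 2.62 FPKM. The list stood above other genes in the camera test (adjusted p = 3.2e-11 over 37 lists). It did not with a correlation between genes estimated from these libraries (adjusted p = 0.32 with an estimated correlation). The KLF10 call was lost without control 1, control 2, TGF-b1 2 or TGF-b1 3 (adjusted p 0.054 to 0.090).

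The components of the pathway itself showed little that passed the test. None of the 16 measured ligands, receptors and SMADs passed in limma, adjusted over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 7, voom called 1 higher, and without control 3 there were 6 higher and 1 lower. Over all 11363 genes tested 2849 were at an unadjusted p under 0.05, the background for each such count here and below. Without control 3, 3280 of them passed, 1408 higher and 1872 lower, the background for each count in that setting. With the GC and length trend also removed 793 passed. The receptor gene TGFBR1 stood at 4.77 and 6.5 FPKM in control and TGF-b1 libraries (adjusted p = 0.082), and TGFB1, which encodes the added cytokine, at 114 ± 13.9 and 108 ± 6.24 FPKM (adjusted p = 0.67). In the list of BMP and ID genes, 1 of 12 members rose, also when adjusted over the list alone, and 3 were higher and 1 lower without control 3. It was BMPR2, a BMP type II receptor, from 7.20 ± 1.19 to 12.9 ± 0.257 FPKM (adjusted p = 0.0039). ID1, a helix-loop-helix inhibitor induced by BMP, was at 50.8 ± 9.60 and 59.1 ± 7.85 FPKM (adjusted p = 0.35). The median of that list was -0.016 and its mean 0.086, and neither list passed the camera test (adjusted p = 0.18 and 0.54).

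Mesenchymal markers moved in part. Of 12 measured members, FN1, CDH2, CALD1 and TPM1 rose and TNC fell, against 4 higher and 2 lower adjusted over the list alone. CDH2, which encodes N-cadherin, rose from 4.96 ± 0.818 to 9.39 ± 0.432 FPKM (log2 change 0.81, SE 0.11, adjusted p = 0.0031) and the actin-binding CALD1 from 6.94 ± 0.816 to 11.5 ± 0.191 FPKM. TNC, the matrix glycoprotein tenascin-C, fell from 20.9 ± 1.16 to 12.8 ± 1.65 FPKM. VIM, which encodes the intermediate filament vimentin, was high in both groups, at 130 ± 7.91 and 141 ± 17.8 FPKM (adjusted p = 0.59). The list mean per library on the log2(FPKM + 1) scale was 3.78 ± 0.027 in control and 3.99 ± 0.017 in TGF-b1 libraries. The exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest it can give. By camera the list did not pass (adjusted p = 0.070), although it did without control 2 (0.024), without TGF-b1 3 (0.049) and with the GC and length trend removed (0.023; adjusted p = 0.22 with an estimated correlation). By fry it passed (adjusted p = 0.0034). The TPM1 call was lost without control 1, TGF-b1 2 or TGF-b1 3 (adjusted p 0.063 to 0.13). CDH2 lies on chromosome 18 at 27950966 to 28177446.

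Epithelial markers and EMT transcription factors had no member past the threshold over all genes. Of 13 measured epithelial markers 0 passed in limma, and 2 higher and 3 lower passed adjusted over the list alone. At an unadjusted p under 0.05 there were 5, voom called 1 higher and 2 lower, and without control 3 there were 2 higher and 4 lower. KRT18, a keratin of simple epithelia, stood at 322 FPKM in control and 227 in TGF-b1 libraries (adjusted p = 0.079) and TJP1, a tight junction protein, at 5.16 and 7.10 (adjusted p = 0.097). CDH1, which encodes E-cadherin, was near the limit of detection in both groups, with 12 fragments summed over the control and 14 over the TGF-b1 libraries, so a small change in it was not detectable at this depth. The epithelial list mean was 4.0 ± 0.062 and 3.88 ± 0.075 (exact permutation p = 0.1), and camera gave an adjusted p of 0.34. Of 7 measured EMT transcription factors 0 passed over all genes in limma, 2 at an unadjusted p under 0.05, 2 higher adjusted over the list alone, 2 higher by voom and 2 higher without control 3. The camera test gave an adjusted p of 0.070, and of 0.014 with the GC and length trend removed (adjusted p = 0.27 with an estimated correlation). By fry these factors passed as a list (adjusted p = 0.022). SNAI1 was at 1.54 ± 0.481 and 2.05 ± 0.171 FPKM (adjusted p = 0.21, and 0.029 with the GC and length trend removed) and ZEB1 at 0.843 ± 0.188 and 1.04 ± 0.0742 FPKM (adjusted p = 0.40). SNAI2 had 8 and 15 fragments in all, and TWIST1 had 0 in both groups.

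Matrix and adhesion genes held several of the changes. Of 11 measured collagens, 3 rose and 0 fell, against 5 and 0 adjusted over the list alone. COL7A1, the anchoring fibril collagen, rose from 0.258 ± 0.011 to 2.35 ± 0.399 FPKM, a ratio of 9.08 (log2 change 1.4 on the compressed scale, adjusted p = 0.00014). COL1A1 rose from 0.633 ± 0.0633 to 2.14 ± 0.274 FPKM and COL4A1, a basement membrane collagen, from 23.1 ± 1.33 to 37.5 ± 1.14 FPKM. The camera test placed the collagens above other genes (adjusted p = 0.023; adjusted p = 0.32 with an estimated correlation), and it did not without control 3 (0.15, with 4 higher and 2 lower) or TGF-b1 1 (0.10), with the replicate number as a block (0.091), with no filter (0.091) or at a minimum of 5 FPKM (0.074). Among 12 integrin genes, ITGAV rose from 63.7 ± 7.93 to 124 ± 2.76 FPKM, ITGA11, a collagen receptor subunit, rose from 0.690 to 2.17 FPKM, and ITGB4, the hemidesmosomal subunit, fell from 2.74 to 1.61 FPKM, with 5 higher and 2 lower adjusted over the list alone and 5 and 3 without control 3. The ITGB4 call was lost with the GC and length trend removed (adjusted p = 0.091) and without control 1, control 2, TGF-b1 1 or TGF-b1 3 (0.058 to 0.14).

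Of 19 matrix glycoproteins and crosslinking enzymes 3 rose and 2 fell, against 5 and 3 adjusted over the list alone and 6 and 3 without control 3. They were FN1, the transglutaminase TGM2 (148 to 225 FPKM), thrombospondin THBS1 (6.91 to 10.6 FPKM), TNC and, named after its value was seen, the laminin chain LAMB3 (105 to 73.3 FPKM). Among 13 matrix proteases and inhibitors 2 rose, ADAM19 among them, and the collagenase MMP1 fell from 3.74 to 2.28 FPKM, the same counts of 2 and 1 as adjusted over the list alone, against 2 and 4 without control 3. That list's median was -0.042 and its mean 0.11. None of the integrin, matrix glycoprotein and protease lists passed camera (adjusted p = 0.13, 0.10 and 0.86), but the matrix glycoproteins did with the GC and length trend removed (0.021; adjusted p = 0.22 with an estimated correlation). By fry all of these lists passed (adjusted p = 0.012, 0.0081 and 0.046). The THBS1 call was lost without control 1 (adjusted p = 0.067), the TGM2 call without control 1, TGF-b1 2 or TGF-b1 3 (0.052 to 0.071), the LAMB3 call without control 1, control 2, TGF-b1 2 or TGF-b1 3 (0.11 to 0.18) and the MMP1 call without any library but control 3 (0.058 to 0.12).

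The actin cytoskeleton list and the list of YAP and TEAD targets stood above other genes. Of 21 actin and contraction genes TPM1 and CALD1 rose and MYL9, a myosin light chain, fell from 4.46 to 2.71 FPKM, against 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.32 with an estimated correlation). Without control 3, where 7 were higher and 2 lower, or TGF-b1 1 the list did not pass (0.074 and 0.11). The MYL9 call was lost with the GC and length trend removed (0.061) and whichever library other than control 3 was left out (0.057 to 0.19); the TPM1 call was lost without control 1, TGF-b1 2 or TGF-b1 3 (0.063 to 0.13). Of 19 YAP and TEAD targets 3 rose and 0 fell, against 8 and 1 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.32 with an estimated correlation), and at a minimum of 5 FPKM the list did not pass (0.062). FOXF2, a forkhead factor, rose from 0.863 to 2.34 FPKM, NT5E from 13.3 to 18.9 FPKM and DLC1 from 3.87 to 5.55 FPKM. The NT5E call was lost without control 1, control 2, TGF-b1 2 or TGF-b1 3 (0.084 to 0.12) and the DLC1 call without any library but control 3 (0.074 to 0.21). Without control 3 there were 8 higher and 1 lower.

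Stemness and cancer stem cell markers did not pass the test as a list. Of 13 measured members 0 rose and 2 fell, against 0 and 3 adjusted over the list alone and 2 and 2 without control 3. ALDH1A3, an aldehyde dehydrogenase of retinoic acid synthesis on chromosome 15 at 100877714 to 100916626, fell from 14.1 ± 0.979 to 8.48 ± 0.275 FPKM (log2 change -0.67, SE 0.090, adjusted p = 0.0030). MYC fell from 33.7 ± 1.69 to 25.3 ± 1.58 FPKM at an adjusted p of 0.049. That call was lost with the GC and length trend removed (adjusted p = 0.13) and on leaving out any library but control 3 (0.079 to 0.18). CD44, a hyaluronan receptor, stood at 102 ± 4.65 and 103 ± 3.05 FPKM (adjusted p = 0.98), KLF4 at 1.39 ± 0.128 and 0.884 ± 0.064 FPKM (adjusted p = 0.093) and POU5F1, which has expressed pseudogenes, at 5.40 ± 0.689 and 4.89 ± 0.861 FPKM (adjusted p = 0.53). POU5F1 also overlaps TCF19 on the opposite strand, named after its value was seen, at 43.2 ± 2.81 and 35.1 ± 3.85 FPKM. Fragments where these genes overlap cannot be told apart, so the POU5F1 value is uncertain. ALDH1A1 had 29 and 28 fragments and SOX2 9 and 8 over the 3 libraries of each group, so that small changes in these were not detectable at this depth, and NANOG and PROM1 had 0 in both groups. The list mean per library was 3.41 ± 0.036 in control and 3.32 ± 0.022 in TGF-b1 libraries (exact permutation p = 0.1, the smallest possible). Its median log2 change was 0.0049 and its mean -0.088, and camera gave a lower direction at an adjusted p of 0.37.

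**Figure D2:**
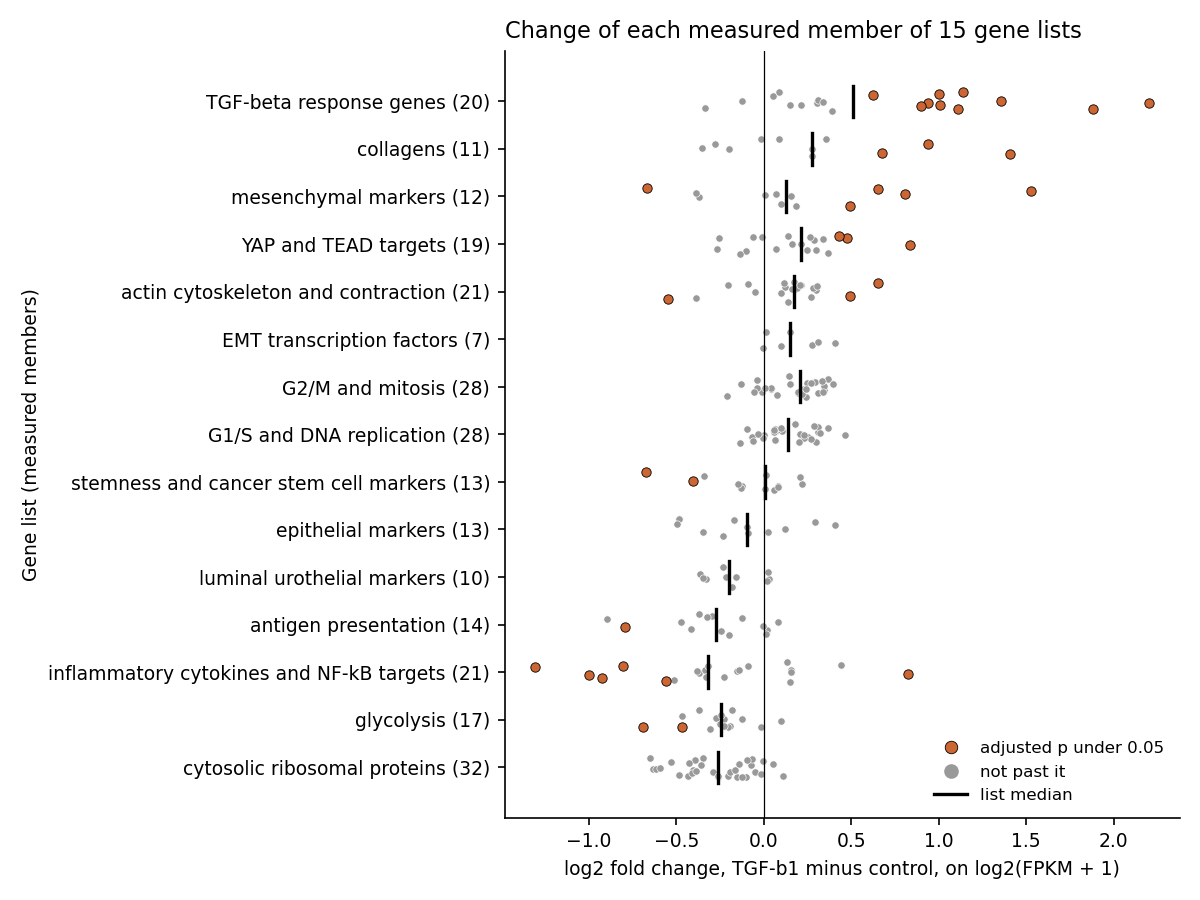
Each point is the log2 fold change of 1 measured gene, TGF-b1 minus control on log2(FPKM + 1), in 15 gene lists. Coloured points passed an adjusted p of 0.05, grey points did not, and black bars are list medians, from 0.51 for TGF-beta response genes to -0.32 for inflammatory cytokines and NF-kB targets.

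Urothelial differentiation markers held no gene past the threshold. Of 3 measured basal markers 0 passed over all genes in limma, 2 at an unadjusted p under 0.05, 2 higher adjusted over the list alone and 2 higher by voom, and EGFR, a growth factor receptor, was at 31.6 and 40.6 FPKM (adjusted p = 0.11). Of 10 luminal markers 0 passed over all genes or adjusted over the list alone, 2 at an unadjusted p under 0.05 and 1 lower by voom. Without control 3 there was 1 basal marker higher and 2 luminal markers lower. The uroplakin UPK1B was at 1.81 and 1.24 FPKM (adjusted p = 0.11). The camera test gave an adjusted p of 0.13 for the basal and 0.070 for the luminal list. Both passed by fry (adjusted p = 0.026 and 0.018).

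Inflammatory cytokines and NF-kB targets were lower as a group. Of 21 measured members, CSF3, IL6, CXCL2 and, named after their values were seen, CCL20 and NFKBIA fell, and CCL2 rose, against 2 higher and 9 lower adjusted over the list alone. IL6, the interleukin on chromosome 7 at 22725884 to 22732002, fell from 21.4 ± 3.71 to 10.2 ± 1.16 FPKM (log2 change -1.0, adjusted p = 0.0030), and overlaps STEAP1B on the opposite strand. The chemokines CXCL2 and CCL20 fell from 20.8 to 10.5 FPKM and from 43.7 to 24.9 FPKM, and NFKBIA, the NF-kB inhibitor, from 126 to 84.9 FPKM. The monocyte chemokine CCL2 rose from 1.39 to 3.26 FPKM. The median log2 change of the list was -0.32 (camera adjusted p = 0.0025; adjusted p = 0.32 with an estimated correlation), and -0.069 with the GC and length trend removed (adjusted p = 0.016; adjusted p = 0.22 with an estimated correlation). With control 3 also left out the list did not pass (median -0.065, adjusted p = 0.057), nor did CXCL2 and NFKBIA (0.063 each), at log2 changes of -0.66 and -0.41 against -0.77 and -0.39 with the trend removed alone. NFKBIA was lost without control 1, control 2, TGF-b1 2 or TGF-b1 3 (adjusted p 0.11 to 0.20), and CCL2 without control 1 (0.051). Without control 3 there were 2 higher and 10 lower members, and with the GC and length trend removed 2 higher and 8 lower.

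Genes of antigen presentation were lower as a list by camera at the preset correlation, but did not pass by fry (adjusted p = 0.075). Of 14 measured members 1 was past the threshold, and 6 were lower adjusted over the list alone. PSMB9, a subunit of the immunoproteasome, fell from 10.6 ± 1.42 to 5.67 ± 0.611 FPKM (log2 change -0.79, adjusted p = 0.0042), and overlaps PSMB8 on the opposite strand. HLA-E was at 96.8 and 71.9 FPKM (adjusted p = 0.085). The camera test gave an adjusted p of 0.0032 (adjusted p = 0.38 with an estimated correlation), with a median log2 change of -0.27. With the GC and length trend removed the median was -0.14 (adjusted p = 0.023; adjusted p = 0.30 with an estimated correlation). Without control 3 there were 7 lower members. Of 15 interferon-stimulated genes 0 passed over all genes in limma, with 4 at an unadjusted p under 0.05, 4 lower adjusted over the list alone, 4 lower by voom and 5 lower without control 3 (camera adjusted p = 0.10). With the GC and length trend removed the list passed as lower (0.0068; adjusted p = 0.21 with an estimated correlation). By fry it passed without that removal (adjusted p = 0.012). Of 9 immune checkpoint ligands only NT5E, the ecto-nucleotidase CD73, rose, from 13.3 to 18.9 FPKM, also when adjusted over the list alone. The NT5E call was lost without control 1, control 2, TGF-b1 2 or TGF-b1 3 (0.084 to 0.12). That list's median was -0.025 and its mean 0.0020 (camera adjusted p = 0.92). CD274, which encodes PD-L1, stayed under the filter, at 0.257 ± 0.0758 and 0.426 ± 0.121 FPKM, or 72 and 121 fragments, and was not tested.

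Cell cycle lists were higher in the main test without any single member past the threshold over all genes or adjusted over the list alone. The median log2 change was 0.14 over 28 genes of G1/S and DNA replication (camera adjusted p = 0.0025; adjusted p = 0.32 with an estimated correlation) and 0.21 over 28 genes of G2/M and mitosis (adjusted p = 0.0017; adjusted p = 0.34 with an estimated correlation). With the GC and length trend removed the medians were 0.18 and 0.11 (adjusted p = 1.4e-08 and 0.0016; adjusted p = 0.086 and 0.22 with an estimated correlation). In that setting 4 G1/S and 0 G2/M genes were higher past the threshold over all genes. CDC6, a replication licensing factor, stood at 18.1 and 22.8 FPKM (adjusted p = 0.088) and TOP2A, a topoisomerase of dividing cells, at 38.0 and 48.9 FPKM (adjusted p = 0.10). At an unadjusted p under 0.05 there were 11 G1/S and 13 G2/M genes, and voom called 5 and 3 of them higher. Without control 3 there were 9 and 14 higher, and the G1/S list had a median of 0.10 (adjusted p = 0.074). Of 14 cell cycle inhibitors GADD45B rose, from 10.9 to 19.2 FPKM, also when adjusted over the list alone. Its call was lost without control 1 (0.057), and 3 members were higher and 5 lower without control 3. That list's median was -0.0047 and its mean 0.0080 (camera adjusted p = 0.91).

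Glycolysis genes and cytosolic ribosomal proteins were lower as lists by camera at the preset correlation. By fry the glycolysis list passed (adjusted p = 0.027) and the ribosomal list did not (0.13). Of 17 glycolysis genes PFKL and ENO2 fell and 0 rose, against 3 lower adjusted over the list alone, with a median log2 change of -0.25 (camera adjusted p = 9.3e-05; adjusted p = 0.33 with an estimated correlation). The phosphofructokinase PFKL fell from 43.5 to 26.3 FPKM and the enolase ENO2 from 26.1 to 18.6 FPKM. Both calls were lost without control 1, control 2, TGF-b1 2 or TGF-b1 3 (0.13 to 0.16 for PFKL and 0.11 to 0.18 for ENO2). Without control 3 there were 12 lower members, where 1872 of all 11363 genes were lower. With the GC and length trend removed there were 3 lower members. Of 32 ribosomal protein genes 0 passed over all genes in limma, 16 at an unadjusted p under 0.05, 14 lower adjusted over the list alone, 13 lower by voom and 18 lower without control 3, with a median of -0.26 (camera adjusted p = 1.7e-05; adjusted p = 0.45 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, which leaves their values uncertain.

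The libraries differed along GC content within groups as well as between them. Over 11292 tested genes with a GC value, the log2 difference of TGF-b1 from control correlated with GC content at r = -0.55, that of control 3 from controls 1 and 2 at r = -0.63 and that of TGF-b1 3 from TGF-b1 1 at r = -0.38. Control 2 against control 1 gave 0.0033. These correlations are across genes, which are not independent replicates. Control 3 correlated with controls 1 and 2 at a mean r of 0.985 and with the TGF-b1 libraries at 0.987, and the first principal component held 54.9% of the variance. The falling lists of ribosomal proteins, glycolysis, antigen presentation and inflammatory genes and the rising cell cycle lists were all measured across this trend. With the trend removed, 16 lists passed camera, these 6 among them, and 0 passed with an estimated correlation. The labels name no batch, and a fit with the replicate number as a block gave 767 genes. Deviations from the group mean correlated between libraries of the same number at 0.25, -0.071 and 0.17 for replicates 1, 2 and 3. The highest correlation with another number was -0.016, 0.057 and 0.069. This does not settle whether the numbers mark pairs.

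**Figure D3:**
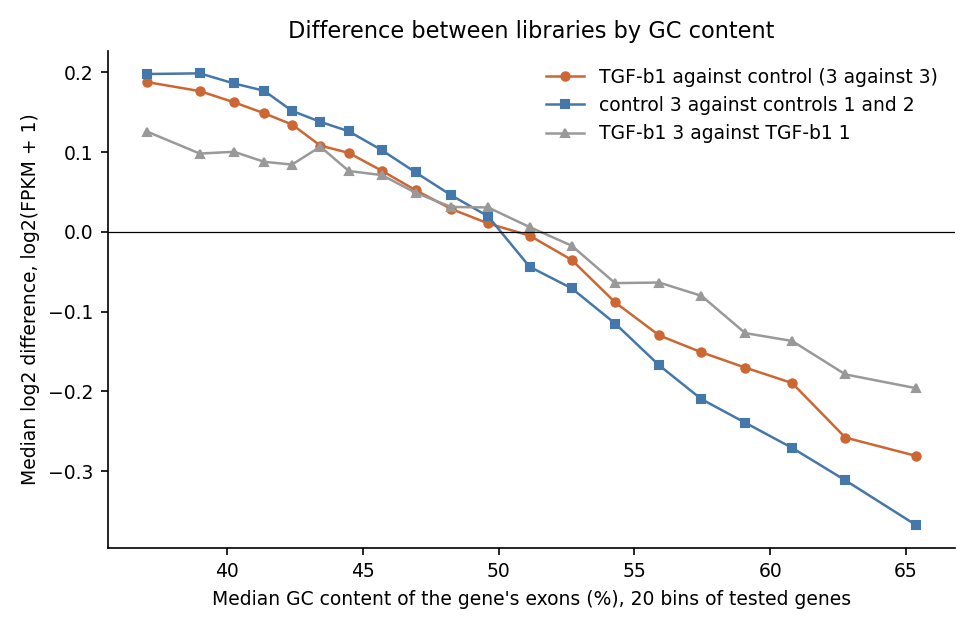
Median log2 difference, on log2(FPKM + 1), in 20 bins of tested genes ordered by the GC content of their exons, for TGF-b1 against control, control 3 against controls 1 and 2, and TGF-b1 3 against TGF-b1 1. The differences run from 0.19 in the lowest to -0.28 in the highest bin for TGF-b1 against control and from 0.20 to -0.37 for control 3.

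Markers of other cell types were nearly absent. Of 16 blood and immune markers 0 passed the filter, and the highest single value was CD8A at 0.438 FPKM. Of 10 endothelial markers 0 passed it, with PECAM1 highest at 0.574 FPKM. Of 12 fibroblast and smooth muscle markers only COL1A1 passed the filter, and of 12 hepatocyte and neural markers only SYP did, at 1.44 and 1.0 FPKM (adjusted p = 0.23). The reference gene ACTB stood at 2373 ± 173 and 2462 ± 245 FPKM (adjusted p = 0.81) and GAPDH at 2463 ± 271 and 2073 ± 154 FPKM (adjusted p = 0.24). GAPDH is itself the middle member of the glycolysis list, so its log2 change, -0.25, is that list's median by construction. The lowest adjusted p of GAPDH over the settings was 0.047. Of 18 housekeeping genes 0 passed over all genes or adjusted over the list alone in limma, 6 at an unadjusted p under 0.05 and 2 lower by voom (camera adjusted p = 0.37). Without control 3, 1 was higher and 6 lower. Genes of the mitochondrial genome took 4.39 to 5.07% of the assigned fragments per library, and 0 of 15 passed over all genes, adjusted over the list alone or by voom, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.92).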

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

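The tests below on control 3, on the inflammatory list, of the GC trend in the G1/S list and of the splits for the count of 277 genes, and the interval of the change in the G1/S median, were chosen only after the result was seen, as was the removal of the GC and length trend.

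Among 45627 genes under the filter, 3 had at least 10 fragments in each TGF-b1 library and at most 3 in each control library, and 1 had the mirror pattern. NKAIN4 had 55 fragments over the TGF-b1 libraries and 2 over the controls. ACTBL2, a close relative of ACTB whose reads the counting can confuse with it, had 47 and 2, and CRYAA, a lens crystallin, had 45 and 5. None of them was tested between groups, and they were chosen after their values were seen.

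The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, 277 genes passed the threshold, and the highest other split gave 3. For changes of at least 2-fold the values were 32 and 3, for genes of the lists 59 and 0, and for lists past the camera test 10 and 5, each again in 1 of 10 splits.

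Control 3 correlated slightly more with the TGF-b1 libraries than with controls 1 and 2, a difference of -0.0024 in mean r. With the GC and length trend removed the difference was 0.0022, which is consistent with that trend as a source. A mislabelled library, or TGF-β1 in the cells of control 3, needs the TGF-β response genes to lie on the TGF-b1 side. Over that list the slope of control 3 on the TGF-b1 change was -0.088 (95% bootstrap interval -0.23 to 0.088), against 0.64 over all tested genes, which argues against both. Why the trend differs between libraries was not tested, and no biological explanation for control 3 was tested.

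The 5 inflammatory genes that fell were still past the threshold with the GC and length trend removed, with log2 changes of -1.05 to -0.39 and a highest adjusted p of 0.048. This argues against the trend as their whole cause. In that setting 2 members of the list were higher and 8 lower. Calls close to the threshold are weak there and in the main test. In the simulation false calls exceeded the share that the threshold allows with the trend removed, with it left in and without a trend. With control 3 also left out CXCL2 and NFKBIA had an adjusted p of 0.063 each, at log2 changes of -0.66 and -0.41 against -0.77 and -0.39. Blood or immune cells in the controls are argued against by their markers, the highest of which in a control library was CD8A at 0.438 FPKM. The median of the list went from -0.32 to -0.069 with the trend removed (95% bootstrap interval -0.44 to 0.027), where camera gave an adjusted p of 0.016 (adjusted p = 0.22 with an estimated correlation), and with control 3 also left out the call was lost (median -0.065, adjusted p = 0.057). For the median, the trend and TGF-β1 cannot be told apart because the members are few and spread widely. An effect of TGF-β1 on the 5 genes stays a hypothesis.

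The G1/S list had a median of 0.176 with the GC and length trend removed (95% bootstrap interval 0.14 to 0.23, adjusted p = 1.4e-08; adjusted p = 0.086 with an estimated correlation), against 0.14 before, which argues against that trend as its whole cause. For a difference between libraries that control 3 shares, leaving control 3 out was set to raise the median by 0.5 of itself or more, but the median fell from 0.14 to 0.10 (change -0.039, 95% bootstrap interval -0.070 to 0.051), which argues against control 3 sharing the whole of the shift. A smaller shift of control 3 in the same direction cannot be told apart from TGF-β1. Across the genes of the list the slope of control 3 on the TGF-b1 change was 0.480 (interval 0.33 to 0.67), between the bounds set for either answer. That slope has controls 1 and 2 on both sides, which raises it by construction. Without control 3 the list had an adjusted p of 0.074, and whether the treated cells divided more is open.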

How the results depend on the processing

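The tests with voom, total-fragment scaling and the GC and length trend removed, alone, with the replicate block or without control 3, were chosen only after the result was seen. The edgeR count test on recovered fragments, listed beforehand, was not run, since the deposited values are FPKM, and voom was run on those fragments instead. The settings differ by construction in the genes tested or the libraries used, but what caused a count to change was not tested. Over protein-coding genes alone 2961 of 10019 were at an unadjusted p under 0.05, against 2849 of 11363 in the main test. The number of genes tested is therefore not the whole reason for the higher count there.

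The main values were 277 genes changed, 130 higher and 147 lower, 32 at least 2-fold, 59 list genes and 10 lists. With 28285 genes and no filter they were 15, 11, 4, 13 and 7 list genes, and with at least 5 FPKM 500 genes, 321 lower. A pseudocount of 0.1 gave 71 at least 2-fold. Protein-coding genes alone gave 846, 295 higher, 551 lower and 113 list genes. The replicate block gave 767, 249 higher and 518 lower. Voom gave 1063, 399 higher, 664 lower, 86 at least 2-fold and 136 list genes. Removing the trend gave 502, 289 higher, 95 list genes and 16 lists, with the block 525, 263, 262 lower and 91, and without control 3 793, 400, 393 and 124. Scaling to total fragments gave 221 lower. Leaving out 1 library gave 124 to 3280 genes, 80 to 1408 higher, 44 to 1872 lower, 34 to 64 at least 2-fold and 36 to 237 list genes. With an estimated correlation 0 lists passed, and the TGF-β response list, at a median of 0.51, had an adjusted p of 0.32. The mesenchymal list passed at 5 FPKM (median 0.34), without control 2 or TGF-b1 3 (0.089 to 0.193 over the settings that leave out 1 library) and with the trend removed, with or without the block (0.20). With each gene scaled to unit variance the stemness list mean differed by -0.19 (exact p = 0.6). The collagen list had an adjusted p of 0.074 at 5 FPKM, 0.091 with no filter, where its median was -0.0022, and 0.091 with the replicate block, and the YAP list 0.062 at 5 FPKM.

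Of 67 named genes past the threshold, 42 stayed past it whichever library was left out, 10 in the same direction under every setting, and 0 turned direction. With no filter 57 of the calls were lost. Without trend or robust estimation those of DLC1, ENO2, LFNG, MYC, MYL9, NFKBIA and PFKL were (adjusted p 0.055 to 0.068), and that of MYC also with a pseudocount of 0.1 (0.051) and quantile normalization (0.056). DLC1 (0.060) and FZD8 (0.090) were lost with the block and the trend removed, and FZD8 without control 3 and the trend (0.063). Directions turned in 7 genes that did not pass the main test. Over the settings that leave out 1 library, including that without control 3 and the trend, ACTB ran from -0.029 to 0.295, CD44 from -0.109 to 0.0347, POU5F1 from -0.236 to 0.0344, TGFB1 from -0.184 to 0.160, STK16 from -0.111 to 0.0844 and CYFIP2 from -0.0717 to 0.0490. CD44 was -0.00724 by median of ratios and -0.093 with the trend removed, with or without the block. ZEB1 was -0.010, TGFB1 0.16 and STK16 0.074 with the trend removed, with or without the block, and TGFB1 was 0.033 by quantile normalization. Scaled to total fragments STK16 was 0.0039 and CYFIP2 0.013.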

Other observations

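The genes and lists below were tested as in the report, and the tests with voom or without the GC and length trend were chosen only after the result was seen.

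Growth factor and early-response genes moved in both directions. Of 21 growth factors, receptors and ligands EPHB2 and PDGFB rose and AREG fell, against 5 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.54). PDGFB, a platelet-derived growth factor chain, rose from 45.5 ± 4.85 to 80.5 ± 7.19 FPKM and AREG, an EGF receptor ligand, fell from 5.97 ± 1.05 to 2.58 ± 0.328 FPKM. Of 22 immediate early and MAPK feedback genes 1 rose and 4 fell, against 2 and 6 adjusted over the list alone (camera adjusted p = 0.18). FOSL1, an AP-1 subunit, fell from 120 to 72.5 FPKM, PHLDA1 fell from 19.6 to 12.4 FPKM, DUSP5 fell as given in the report, MYC fell at an adjusted p of 0.049 and the stress factor ATF3 rose from 3.56 to 5.68 FPKM. Of 9 Notch genes LFNG, a glycosyltransferase of Notch, rose from 5.07 to 8.51 FPKM, against 2 higher and 1 lower adjusted over the list alone, and the list's median was -0.062 and its mean 0.0091, with a lower direction by camera (adjusted p = 0.91). Of 15 Wnt genes WNT9A rose from 0.947 to 2.13 FPKM and the receptor FZD8 fell from 2.61 to 1.39 FPKM, against 2 and 2 adjusted over the list alone (camera adjusted p = 0.55). The ATF3 call was lost without control 1 or TGF-b1 3 (0.052 to 0.059), that of LFNG without TGF-b1 1 or TGF-b1 2 (0.057 to 0.096), that of FZD8 without control 1, control 2, TGF-b1 2 or TGF-b1 3 (0.083 to 0.14), and that of MYC without any library but control 3 (0.079 to 0.18). Without control 3 the numbers higher and lower were 7 and 5 for growth factors, 2 and 8 for early-response genes, 2 and 2 for Notch and 2 and 2 for Wnt genes. With the GC and length trend removed they were 4 and 2, 3 and 3, 1 and 0, and 2 and 2. There the median of the early-response genes went from -0.11 to 0.084 and that of the Notch genes to 0.032, and camera turned to a higher direction for these and the Wnt genes, without any passing (0.52, 0.24 and 0.83).

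Stress and metabolic lists held few calls, and none of those below passed camera in the main test. Of 19 hypoxia genes ANGPTL4 rose, DDIT4, an mTOR inhibitor, fell from 82.4 ± 13.1 to 43.6 ± 7.32 FPKM and NDRG1 fell from 5.01 to 3.26 FPKM, against 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.18). Of 24 genes of the unfolded protein and amino acid responses ATF3 rose and 2 fell, against 2 and 5 adjusted over the list alone (0.35): CEBPB, a transcription factor, from 85.6 to 46.4 FPKM and SLC7A5, an amino acid transporter, from 158 to 102 FPKM. Of 17 NRF2 targets OSGIN1 fell from 6.27 to 4.11 FPKM, against 3 lower adjusted over the list alone (0.13), and the list passed as lower with the GC and length trend removed (0.041; adjusted p = 0.27 with an estimated correlation). Of 21 cholesterol synthesis genes, 4 metallothioneins and 7 replication-dependent histones 0 passed over all genes in limma, with 4, 1 and 2 at an unadjusted p under 0.05, 1, 0 and 0 lower by voom, and 0, 1 and 0 adjusted over the list alone (camera adjusted p = 0.54, 0.26 and 0.54). The calls of DDIT4 (without control 2, 0.051), CEBPB (without control 1, 0.060), SLC7A5 (without control 1 or TGF-b1 2, 0.064 to 0.066) and ATF3 (without control 1 or TGF-b1 3, 0.052 to 0.059) were lost in those settings. Those of NDRG1 (0.066 to 0.13) and OSGIN1 (0.092 to 0.11) were lost without control 1, control 2, TGF-b1 2 or TGF-b1 3, and that of OSGIN1 also with the GC and length trend removed (log2 change -0.26, adjusted p = 0.078). Without control 3 the numbers higher and lower were 2 and 4 for hypoxia, 2 and 9 for unfolded protein response, 0 and 4 for NRF2, 1 and 5 for cholesterol and 0 and 2 for histone genes.

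The first principal component placed control 3 at 1.63, between controls 1 and 2 at -18.7 and -22.0 and the TGF-b1 libraries at 6.46 to 18.5. The median change over all tested genes was 0.012 on the log2(FPKM + 1) scale and 0.0015 to 0.040 under the other scalings.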
